A study of Mus musculus with 54 samples.

How the data were processed

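The deposited values were log2 expression values per probe set, background-corrected, normalized and summarised by the authors. Per the submitters' processing notes, the authors worked in R 2.6.1 with affy 1.16.0, named RMA as well as GCRMA 2.10.0, and used limma 2.12.0. The notes leave open which method made the deposited values. The lowest value differed by tissue, as it would if the tissues had been normalized apart. Per the labels' protocols, RNA was extracted with TRIzol, 12 mice per strain were kept 6 per cage, 6 mice per strain were tested over 5 days, and scores of 3 sessions were averaged. The growth protocol says how many strains there were but leaves C57BL10/J out of its list, while the sample labels include it. Hybridization batch and scan date are not given in the sources used here, so no batch was tested.

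From these values everything was recomputed with limma 3.58.1 in R 4.3.3. Of 45101 probe sets, 64 control probe sets were set aside, 34945 had 1 gene symbol, 932 had several and 9160 were unnamed here, not without a gene. Each of 18193 genes was represented by its brightest probe set over the 54 arrays (9010 genes had several). A gene was tested in a tissue when it lay above the array's 40th percentile on at least 3 arrays of that tissue. Within a tissue the model had a term for strain and a term for testing on the 18 arrays. Across tissues it had strain within tissue and testing within tissue on all 54 arrays, taken as independent although mice were shared across tissues (below). Limma's moderated tests used an intensity trend, were two-sided, and called a gene at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. Fold counts are of called genes over 2-fold.

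Gene lists, 35 in number with 389 genes of which 354 had a probe set, were fixed before the data were examined, as were the models, the filter, the choice of probe set, the alternatives (other than those described as added), and the rule for naming genes. Lists were tested with camera at a preset correlation of 0.01, with the estimated correlation beside it, and, for the 6-strain comparison, with Fisher's exact test (two-sided) against all genes tested. List p-values were adjusted over the lists of a comparison. In parentheses after a list, the values are in the order count adjusted over the list alone (where left out, equal to the count called), median log2 difference, camera adjusted p and adjusted p with an estimated correlation. In no list that passed did the median, the mean and the test differ in sign. Genes named are, per strain, those with the 3 highest and 3 lowest mean differences over tissues among genes called the same way in all 3 tissues. For the 6-strain test they are the 5 widest ranges, for testing the 5 smallest p, for tissues the 10 highest, for the interactions the 10 or 3 smallest p, for lists up to 4 members with the smallest p, and Pdxdc1 throughout. Which of those list members to name, their values in tissues where they were not among the 4, Ttr in C57BL10/J hippocampus, and the repeated strain values of genes named elsewhere were chosen after their values were seen.

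By the mouse numbers in the labels the tissues of a strain shared mice, since 2 untested pools of 3 in each of 3 tissues exceed the 6 untested mice, and 3 tested pools of 3 exceed the 6 tested mice. Which pool of a tissue matches which of another is not given in the sources used here. The correlation of deviations between arrays of the same strain and number had a median of -3.05e-04 between hippocampus and striatum (-0.44 to 0.44), 0.10 between hippocampus and brainstem (-0.13 to 0.22) and -0.02 between striatum and brainstem (-0.21 to 0.19), with 4, 9 and 1 of 18 pairs over 0.1, so replicate number was no term of the model. Some lists kept the order of the arrays across tissues, such as chaperone genes in BalbC/J. The models across tissues and the numbers that independent lists would share take no account of the shared mice, so p-values across tissues are not exact and agreement between tissues is not independent evidence. With replicate number as a block, which stands for the shared mice only if the numbers match, the strain by tissue test called 2002 genes in place of 2294, the tissue comparisons 11301 in hippocampus, 11860 in striatum and 11711 in brainstem, and the 6-strain comparison called 3607 genes in hippocampus, 3013 in striatum and 2667 in brainstem.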

Results

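The data are gene expression arrays (Affymetrix mouse 3' arrays, 45101 probe sets) of 3 brain tissues from male mice of 6 inbred strains. The strains were C3H HeJ, BalbC/J, C57BL10/J, C57BLKS/J, C57L/J and C57BL6/J. The tissues were hippocampus, striatum and brainstem. Each strain and tissue had 3 arrays, giving 18 arrays per tissue and 54 in all, and each array carried RNA pooled from 3 mice. In each strain and tissue 1 array came from mice tested for prepulse inhibition (the weakening of a startle response by a softer sound played just before the loud one) and 2 from untested mice. The series title names Pdxdc1, the gene of pyridoxal-dependent decarboxylase domain containing 1, beside prepulse inhibition. The labels give no inhibition score for any strain, so strains were not ranked by behaviour here.

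Deposited values were on a log2 scale, from -0.20 to 16.89, with array medians of 4.53 to 4.72 in hippocampus, 4.17 to 4.31 in striatum and 4.43 to 4.57 in brainstem. The 40th percentile of an array, used as the level a signal had to pass to be tested, lay between 3.13 and 3.47. The lowest value of an array was -0.20 to -0.15 in hippocampus, -0.02 to 0.03 in striatum and -0.12 to -0.08 in brainstem, so the tissues had different floors and levels are compared across tissues with that limit. Every array but 1 correlated best with another array of its own strain and tissue. The exception was the tested C57L/J striatum array. The second untested C3H HeJ brainstem array had the lowest correlation with its own strain (r = 0.956), and the tested BalbC/J striatum array the next lowest (r = 0.977). Arrays have no read depth, and their number, 3 per strain and tissue, limits the precision. Values below are log2 differences with standard errors from limma, or means with SD over 3 arrays.

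The question the series title poses is how Pdxdc1 expression differs between strains. On its brightest probe set, Pdxdc1, on chromosome 16, was lower in C3H HeJ than in C57BL6/J by -1.44 ± 0.15 in hippocampus, -2.11 ± 0.21 in striatum and -1.72 ± 0.15 in brainstem (adjusted p = 7.24e-06, 9.61e-06 and 2.14e-06), or 2.71, 4.30 and 3.29 times lower. BalbC/J was lower by -1.08 ± 0.15, -1.29 ± 0.21 and -1.54 ± 0.15 in the same order (adjusted p = 1.52e-04, 0.00112 and 8.21e-06). In the other C57 strains Pdxdc1 was not called different from C57BL6/J. The C57BL10/J differences were -0.32, 0.06 and -0.19 (adjusted p = 0.306, 0.957 and 0.533), those of C57BLKS/J -0.32, 0.07 and 0.01 (0.268, 0.999 and 1.00), and those of C57L/J 0.00, -0.05 and -0.19 (0.995, 0.904 and 0.671). Hippocampal Pdxdc1 levels were 7.47 ± 0.24 in C3H HeJ, 7.83 ± 0.25 in BalbC/J and 8.91 ± 0.14 in C57BL6/J (SD, n = 3 arrays each). Across all 6 strains the moderated F test called Pdxdc1 in each tissue, with a range of strain means of 1.44 in hippocampus, 2.17 in striatum and 1.73 in brainstem (adjusted p = 7.71e-06, 5.42e-06 and 7.85e-07).

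The other 3 probe sets of Pdxdc1, called B, C and D here in falling order of mean level, gave different sizes and, in 1 case, the opposite direction. The brightest probe set was so only by its mean over all arrays, and it was not the brightest in any strain. In hippocampus it was at 8.91 in C57BL6/J against 9.92 on probe set B, and at 7.47 in C3H HeJ against 10.57 on probe set C. Results for Pdxdc1 given without a named probe set rest on it in every comparison. Probe set B was lower in C3H HeJ by -6.62, -6.60 and -7.26 and in BalbC/J by -6.93, -6.54 and -7.03 in hippocampus, striatum and brainstem. Its level fell from 9.92, 9.59 and 10.33 in C57BL6/J to 3.30, 3.00 and 3.08 in C3H HeJ. Probe set C was higher in C3H HeJ by 7.82, 7.19 and 7.62 and in BalbC/J by 7.94, 7.68 and 7.99. On that probe set the C57BL6/J arrays lay at the floor, at 2.75, 2.75 and 2.95, with 0 of their arrays above the 40th percentile. Probe set D was lower in C3H HeJ by -0.83, -0.77 and -2.26 and in BalbC/J by -0.76, -0.34 and -2.31, with the BalbC/J striatum difference not called (adjusted p = 0.210). The mean of the 4 probe sets gave BalbC/J differences of -0.21 in hippocampus and -0.12 in striatum, neither called, and ended the 6-strain call in hippocampus, where the range fell from 1.44 to 0.27. Among the 11 neighbours of Pdxdc1 listed on the same chromosome, 4 of 11 measured in hippocampus, 3 of 10 in striatum and 4 of 10 in brainstem differed among strains (5, 5 and 6 adjusted over the list alone, Fisher's exact adjusted p = 0.903, 1.00 and 0.589). Parn, a poly(A) ribonuclease gene, was lower in BalbC/J by -1.04, -0.83 and -0.53. Marf1, a regulator of RNA in meiosis, was higher in C3H HeJ by 0.91, 1.31 and 0.83.

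**Figure D1:**
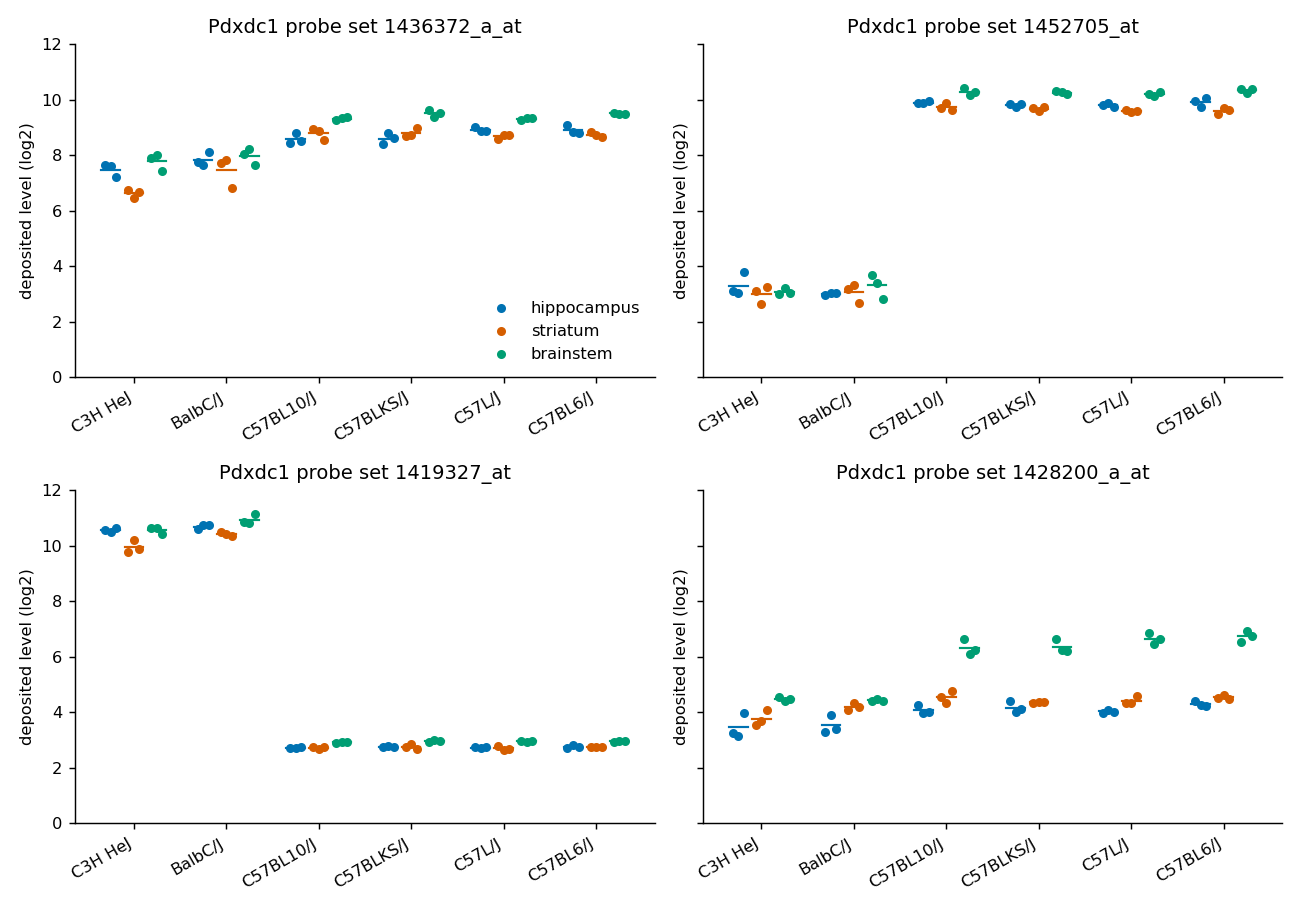
Log2 expression (vertical axis) of the 4 Pdxdc1 probe sets by strain (horizontal axis) in hippocampus, striatum and brainstem, with a point per array. On probe set C, C57BL6/J averaged 2.75, 2.75 and 2.95 while C3H HeJ averaged 10.57, 9.95 and 10.57, and on probe set B the order of these strains was opposite.

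The 6-strain comparison asked which genes vary with genetic background in each tissue. It called 3838 of 12315 genes in hippocampus, 3228 of 12320 in striatum and 2872 of 12484 in brainstem, of which 608, 816 and 594 ranged over more than 2-fold. Strain took 71.6%, 64.8% and 66.6% of the variance (chance 29.4%). The largest range in hippocampus was that of Baiap2l1, an actin-bundling adaptor, at 8.04 (adjusted p = 1.43e-18). Its level was 9.74 in C3H HeJ and 10.25 in BalbC/J against 2.22 to 2.25 in the C57 strains. Rpgrip1, known from photoreceptor cilia, ranged over 7.39, 7.92 and 7.83 in the 3 tissues, but over 0.17, 0.06 and 0.11, not called, on its next brightest probe set. Stk25, a serine/threonine kinase gene, ranged over 7.25, 7.01 and 7.32 and was lowest in C57L/J. Erdr1, a pseudoautosomal gene, ranged over 6.79, 8.57 and 7.59, again lowest in C57L/J. Further wide ranges were those of Gm13306 (7.63 in hippocampus and 7.43 in striatum), the microRNA gene Mir1931 (6.87 in striatum), Tmem87a (7.05 in brainstem) and Gdpd3 (6.66 in brainstem). Leaving out the second untested C3H HeJ brainstem array raised the brainstem count from 2872 to 4701. The p-values measure the spread between pools on arrays, not between single mice.

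Genes of defined function were counted among these strain calls. Hippocampal marker genes differed among strains in hippocampus more often than other genes, with 12 of 14 called (12 adjusted over the list alone, Fisher's exact adjusted p = 0.00134). Oligodendrocyte markers did so in hippocampus, 9 of 10 called (9, 0.00347), with 7 of 10 in striatum (9, 0.0816) and 5 of 10 in brainstem (7, 0.498). Fisher's test takes list members as independent, whereas their estimated correlation in hippocampus was 0.32 for hippocampal and 0.64 for oligodendrocyte markers. No strain contrast of these 2 lists in hippocampus passed camera at those values (adjusted p = 0.624 to 0.853 for those that passed at the preset one). In the same tissue cortical markers had 5 of 7 called (5, 0.198) and thalamic markers 0 of 6 (0, 0.47), the latter uneven between arrays of a strain (0.69 and -0.25 from the tissue median on the untested BalbC/J arrays). Microglial markers differed in striatum, 8 of 10 called (8, 0.0205), beside 7 of 10 in hippocampus (8, 0.116) and 5 of 10 in brainstem (7, 0.498). No strain contrast of the microglial list in striatum passed camera under either setting. Genes already known to vary between inbred strains passed in brainstem, 7 of 9 called (7, 0.0273), with 7 of 9 in hippocampus (8, 0.0634) and 6 of 9 in striatum (8, 0.111). Of 18 candidate genes for prepulse inhibition or schizophrenia, 5, 8 and 3 were called in hippocampus, striatum and brainstem (5, 9 and 3 adjusted over the list alone, Fisher's exact adjusted p = 1.00, 0.605 and 0.941). Among these, Rgs4, a regulator of G-protein signalling, was lower in C3H HeJ striatum by -0.75 ± 0.08, Bdnf, a neurotrophin, lower in C3H HeJ hippocampus by -1.32 ± 0.14, and Fabp7, a fatty acid binding protein, higher in BalbC/J striatum by 1.02 ± 0.21. GABA-A receptor subunits had 5 of 9, 6 of 9 and 2 of 10 called (5, 8 and 3 adjusted over the list alone, the lowest Fisher's exact adjusted p being 0.111, in striatum), led by Gabra2. No acetylcholine signalling gene was called by limma, 0 of 6, 0 of 5 and 0 of 7, and Ache had the smallest p in hippocampus and striatum.

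The comparison of C3H HeJ with C57BL6/J concerned the strain with the most calls against C57BL6/J in each tissue. Tmem87a, which encodes a Golgi membrane protein, was higher in C3H HeJ by 5.84 ± 0.11 in hippocampus, 6.20 ± 0.21 in striatum and 6.07 ± 0.13 in brainstem (adjusted p = 2.06e-14, 1.14e-10 and 7.85e-13), where C57BL6/J lay at the floor. Cap1, an actin regulator, was higher by 3.83 ± 0.18, 4.75 ± 0.37 and 3.37 ± 0.07, and Rbm45, an RNA-binding protein gene, by 4.17 ± 0.43, 3.04 ± 0.52 and 3.59 ± 0.13. Rpgrip1 was lower by -7.08, -7.03 and -7.83, although its next brightest probe set showed differences of 0.08, 0.01 and -0.04. Etnppl, which encodes a pyridoxal phosphate-dependent lyase of ethanolamine phosphate, was lower by -6.34 ± 0.52, -6.25 ± 0.50 and -3.87 ± 0.16. Its level in C57BL6/J was 9.25, 9.25 and 11.2, and its next brightest probe set was also called lower in each tissue. Gm19439 was lower by -4.88, -6.44 and -6.14. In all, 2212 genes were called in hippocampus (925 higher, 1287 lower), 2167 in striatum (1538 higher, 629 lower) and 2408 in brainstem (1446 higher, 962 lower), with 260, 295 and 293 over 2-fold. The genes called in all 3 tissues were 265 higher and 251 lower of 11605, where independent lists would share 14.1 and 5.11. The split depended on scaling, with 1191 higher and 817 lower in striatum and 979 and 1261 in brainstem after quantile normalization, and 730 and 1355 in brainstem after median centring. The striatum count fell to 1425 without the first untested C3H HeJ array and to 1397 and 1285 without the first and the second untested C57BL6/J arrays. The brainstem count fell to 1543, 1404 and 1567 without the tested, first untested and second untested C57BL6/J arrays.

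Oligodendrocyte markers were lower in C3H HeJ than in C57BL6/J. The list had 0 higher and 7 lower of 10 called in hippocampus (9 adjusted over the list alone, median -0.59, camera adjusted p = 0.00614, adjusted p = 0.796 with an estimated correlation). In striatum it had 0 and 7 (8, -0.63, 8.50e-07, 0.312) and in brainstem 1 and 6 (8, -0.43, 0.0108, 0.657). Mog, a myelin glycoprotein gene, was lower by -0.75, -0.59 and -0.72, and Mobp, which encodes myelin-associated oligodendrocyte basic protein, by -0.68, -0.65 and -0.35. On their brightest probe sets the classical MHC genes H2-D1 and H2-K1 were lower by -4.28, -2.67 and -5.89 and by -4.03, -2.97 and -4.42. Whether sequence variants under the probes lowered these values, and with them the list below, was not tested. As a list, MHC and antigen presentation genes had 0 higher and 2 lower of 5 in striatum (median -0.27, adjusted p = 0.00205, 0.147 with an estimated correlation) and 0 and 3 of 8 in brainstem (-0.25, 0.00472, 0.657). The 3 measured Y-linked genes were higher in every tissue (3 and 0 of 3 called, camera adjusted p = 1.86e-05, 4.60e-05 and 2.78e-04, adjusted p = 0.0882, 0.123 and 0.156 with an estimated correlation). Kdm5d was higher by 1.19, 1.72 and 1.25, Eif2s3y by 1.14, 1.38 and 1.51, and Uty by 1.71, 1.74 and 1.39. The complement gene C1qc, a microglial marker, was lower by -2.31 ± 0.15, -2.04 ± 0.12 and -2.39 ± 0.17. Glucocorticoid-responsive genes were lower in striatum, 0 and 5 of 14 (6, median -0.45, 4.60e-05, 0.417), led by Arrdc2 at -2.03 ± 0.36. Brainstem activity-regulated genes were higher, 7 and 0 of 16 (10, 0.64, 0.0134, 0.657), with Fos at 1.24 ± 0.24. Circadian genes there were also higher, 4 and 0 of 13 (5, 0.32, 0.0152, 0.657). Bhlhe41, a repressor in the clock, was lower on its brightest probe set by -3.86 ± 0.19 in hippocampus and -5.97 ± 0.33 in striatum. In brainstem Glra1, the adult glycine receptor subunit whose loss exaggerates startle, was lower by -1.72 ± 0.28, and the glycine signalling list had 0 and 2 of 7 (-0.40, 0.0304, 0.657). Beside these brainstem values, cerebellar markers were higher in C3H HeJ, 1 and 0 of 9 (5, median 1.55, 0.0260, 0.744), brainstem markers lower, 0 and 1 of 15 (-0.27, 0.0231, 0.744), and microglial and oligodendrocyte precursor markers lower, 0 and 2 of 10 (-0.14, 0.0392, 0.744) and 0 and 3 of 6 (-0.42, 0.0201, 0.657). On 1 of the 3 C3H HeJ brainstem arrays, the second untested, cerebellar markers stood 4.23 above the median of all brainstem arrays. Without it, 7 of these brainstem list calls ended: activity-regulated (camera adjusted p = 0.140), circadian (0.396), glycine signalling (0.140), cerebellar (0.660), brainstem (0.939), microglial (0.660) and oligodendrocyte precursor (0.0515). The brainstem oligodendrocyte list still passed without it, but its median shrank from -0.43 to -0.20 (0 and 4 called, 0.0102). The oligodendrocyte call in hippocampus ended without the tested C57BL6/J array (0.0602). The hippocampal calls of this list in C57BL10/J and C57BLKS/J (below) ended without that array too, while that in BalbC/J held. These contrasts share the same C57BL6/J arrays, so their common direction is not a separate finding in each strain. Medians of the MHC list, which has few members, moved with single arrays from -0.12 to -0.62 in striatum and from -0.135 to -0.42 in brainstem.

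BalbC/J shared several of these levels. Tmem87a was higher than in C57BL6/J by 5.95, 5.96 and 7.03 and Cap1 by 3.93, 4.82 and 3.52. AI506816, an uncharacterised locus, was higher by 5.86 ± 0.06, 2.66 ± 0.17 and 5.79 ± 0.04, with the 5 other strains at the floor. Rps9, a ribosomal protein gene, was lower by -5.22, -5.30 and -5.29 on its brightest probe set, but its next brightest probe set differed by only -0.08, 0.07 and -0.03. Rpgrip1 was lower by -6.79, -7.59 and -7.70, while its next probe set showed 0.04, -0.01 and -0.05. Mid1, an X-linked ubiquitin ligase gene, was lower by -5.43, -5.92 and -4.11. Its C57BL6/J level was 7.64 ± 0.75 in hippocampus and 6.04 ± 1.05 in brainstem (SD, n = 3), and each of the other 5 strains lay between 1.92 and 2.48. The counts were 1854 in hippocampus (775 higher, 1079 lower), 946 in striatum (513, 433) and 1534 in brainstem (1056, 478), with 225, 235 and 226 over 2-fold. The genes called in all 3 tissues were 188 higher and 178 lower, where independent lists would share 2.82 and 1.47. After quantile normalization the brainstem split was 737 higher and 581 lower. The striatum count fell to 578 and 584 without the first and second untested C57BL6/J arrays. The brainstem count rose to 3157 without the second untested C3H HeJ array and fell to 1018 and 992 without the tested and first untested BalbC/J arrays, and to 971 and 1002 without the tested and first untested C57BL6/J arrays.

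Chaperone genes were higher in BalbC/J, with 5 higher and 0 lower of 14 in hippocampus (6 adjusted over the list alone, median 0.21, camera adjusted p = 8.68e-04, adjusted p = 0.683 with an estimated correlation). They had 4 and 0 in striatum (7, 0.33, 6.42e-06, 0.595) and 6 and 0 in brainstem (6, 0.27, 0.00335, 0.835). The BalbC/J arrays were uneven. On the tested array the list stood 0.55, 1.12 and 0.84 above the tissue median, against 0.27, 0.57 and 0.51 on the first untested and 0.07, 0.12 and 0.26 on the second, and activity-regulated genes were also highest on the tested array (0.46, 0.49 and 0.35). Markers of neighbouring tissue differed between these arrays too. In the same order of arrays, cerebellar markers stood at 1.04, 1.13 and 0.09 from the median in BalbC/J brainstem, against -0.90, -0.64 and -0.42 in C57BL6/J. In BalbC/J striatum cortical markers stood at 0.92, -0.10 and 0.02 and interneuron markers at 0.57, -0.22 and -0.35. A strain effect on chaperone genes was therefore not separated from dissection. Without that array the chaperone list had 2, 4 and 3 genes called higher, medians of 0.12, 0.31 and 0.26, and camera adjusted p = 0.0466, 0.00113 and 0.0111. Without the tested C57BL6/J brainstem array its brainstem median was 0.18, with 1 gene called (0.0247). Hspa5, the endoplasmic reticulum chaperone BiP, was higher by 0.47 ± 0.11, 0.50 ± 0.08 and 0.39 ± 0.07. The inducible Hspa1a and Hspa1b were higher in brainstem by 1.95 and 2.46 (adjusted p = 0.0107 and 0.0323). Oligodendrocyte markers were lower in hippocampus, 0 and 7 of 10 (9, -0.78, 6.86e-05, 0.683), and in striatum, 0 and 3 (7, -0.36, 0.0123, 0.870), with hippocampal Mog at -1.29 and Mag, another myelin glycoprotein gene, at -1.10. Hippocampal markers were lower in hippocampus, 1 and 5 of 14 (8, -0.30, 0.0197, 0.853), where Tdo2, a tryptophan dioxygenase of granule cells, was lower by -1.78 ± 0.16 and C1ql2, a synaptic C1q-like protein gene, by -1.64 ± 0.14. On the tested, first and second untested BalbC/J hippocampus arrays hippocampal markers stood at -0.34, -0.35 and -0.15 and thalamic markers at 0.49, 0.69 and -0.25 from the tissue median, and on the tested C57BL6/J array at 0.21 and 0.65. Astrocyte markers were higher there, 1 and 0 of 10 (4, 0.12, 0.0479, 0.610). Glucocorticoid-responsive genes were lower in hippocampus, 1 and 3 of 14 (-0.36, 0.0479, 0.882), and in striatum, 0 and 2 (4, -0.37, 0.00538, 0.870), with Arrdc2 at -1.94 and -1.86. Choroid plexus markers were lower in brainstem, 0 and 1 of 9 (-0.91, 0.00992, 0.898). Several of these calls rested on single arrays. In hippocampus the astrocyte and glucocorticoid calls each ended on leaving out any 1 of 8 arrays (adjusted p up to 0.280 and 0.173) and the hippocampal marker call without the tested C57BL6/J array (0.0681). The striatum oligodendrocyte call ended without the second untested array of BalbC/J or of C57BL6/J (up to 0.110), and the choroid plexus call without the first untested BalbC/J array (0.123). Maob, a monoamine oxidase gene, was lower in hippocampus by -0.83 ± 0.14 and in striatum by -0.76 ± 0.12, and Ddc, the aromatic amino acid decarboxylase and a pyridoxal phosphate enzyme, by -0.86 ± 0.19 and -0.70 ± 0.16.

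C57BL10/J, the closest strain to C57BL6/J by calls summed over tissues, still differed by large amounts at a few genes. Cap1 was higher by 3.92, 4.61 and 3.41, and its next brightest probe set was called higher too. Wdfy1, an endosomal phosphoinositide-binding protein gene, was higher by 2.25, 2.50 and 2.87. Casp9, the initiator caspase, was higher by 1.96 ± 0.09, 2.94 ± 0.17 and 1.87 ± 0.13. Pttg1, which encodes securin, was lower by -5.49, -4.41 and -5.43, and 5730409E04Rik by -4.79, -4.25 and -5.51, a locus that the other 5 strains expressed at 9.28 to 10.19. Mid1 was also lower, as in every strain against C57BL6/J. Glra1 in brainstem was lower by -3.05 ± 0.28. The calls numbered 277 in hippocampus (84 higher, 193 lower), 66 in striatum (36, 30) and 343 in brainstem (217, 126), with 29, 30 and 27 over 2-fold. The genes called in all 3 tissues were 14 higher and 16 lower, where independent lists would share 0.00454 and 0.00477. Quantile normalization gave 129 higher and 131 lower in hippocampus and 161 and 151 in brainstem, and median centring 101 and 93 in brainstem. In hippocampus the counts were 135 without the tested C57BL10/J array, 90 without its second untested array, and 426 and 96 without the tested and second untested C57BL6/J arrays. In striatum they were 38 without the first untested C57BL10/J array and 36 and 40 without the first and second untested C57BL6/J arrays. In brainstem they were 150, 119 and 178 without the tested, first and second untested C57BL10/J arrays, 205, 105 and 135 without those of C57BL6/J in the same order, and 1517 without the second untested C3H HeJ array.

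Among gene lists, activity-regulated genes were lower in C57BL10/J striatum without any member called by limma over all genes (0 of 16, 7 adjusted over the list alone, median -0.58, camera adjusted p = 1.73e-08, adjusted p = 0.102 with an estimated correlation). Egr2 and Junb, immediate early transcription factor genes, stood at -1.42 ± 0.34 and -1.20 ± 0.34 there. The list was not lower on every array. The tested, first and second untested C57BL10/J arrays stood at 0.03, -0.32 and -0.53 from the striatum median and those of C57BL6/J at -0.01, -0.01 and 0.49, and without the second untested C57BL10/J array the median was -0.38 (camera adjusted p = 2.48e-06). Dissection markers differed between the same arrays, with cortical markers at -0.09, 0.45 and 0.26 against -0.46, -1.003 and -0.10 in C57BL6/J, and interneuron markers at 0.21, 0.62 and 0.26 against -0.14, -0.42 and 0.01. Oligodendrocyte markers were lower in hippocampus, 0 and 1 of 10 (5, -0.34, 0.0105, 0.760), with Opalin, a myelin protein gene, at -0.58 ± 0.14. Neuronal markers were higher in hippocampus, 0 of 10 called (0.07, 0.0105, 0.727), and in brainstem, 1 and 0 of 10 (3, 0.14, 0.0150, 0.0887). Choroid plexus markers were higher in hippocampus with 0 of 8 called (median 1.56, 0.0134, 0.760), and the choroid plexus transcript Ttr differed by 1.10, less than its standard error. In hippocampus the oligodendrocyte call ended without the tested array of C57BL10/J or of C57BL6/J (adjusted p up to 0.235), the neuronal call without either untested C57BL6/J array (up to 0.136), and the choroid plexus call without either untested C57BL10/J array or the first untested C57BL6/J array (up to 0.136).

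In C57BLKS/J, Cap1 was higher by 3.90, 4.64 and 3.43 and Wdfy1 by 2.31, 2.52 and 2.98. Pi4kb, a phosphatidylinositol kinase gene, was higher by 2.43 in striatum and 3.22 in brainstem on its brightest probe set, and was also called higher in hippocampus (level 8.46 against 6.34). On its next brightest probe set it differed by 0.01, 0.46 and 0.01, not called. Etnppl was lower by -6.05, -5.25 and -1.37 ± 0.16, with the next probe set called lower too. Tmem267, a membrane protein gene, was lower by -5.61, -6.37 and -5.75, and Mid1 lower again. Bhlhe41 was lower by -3.88 ± 0.19 in hippocampus and -5.94 ± 0.33 in striatum, and Glra1 in brainstem by -3.53 ± 0.28. The counts were 686 in hippocampus (234 higher, 452 lower), 268 in striatum (147, 121) and 342 in brainstem (178, 164), with 100, 92 and 78 over 2-fold. The genes called in all 3 tissues were 54 higher and 60 lower, where independent lists would share 0.0411 and 0.0613. Quantile normalization gave 302 higher and 353 lower in hippocampus. Oligodendrocyte markers were lower in hippocampus, 0 and 3 of 10 (4 adjusted over the list alone, median -0.36, camera adjusted p = 0.00429, adjusted p = 0.624 with an estimated correlation), and in striatum, 0 and 1 (1, -0.15, 0.00648, 0.860), with Opalin at -1.30 and -0.90. Glucocorticoid-responsive genes were lower in striatum, 0 and 1 of 14 (5, -0.29, 1.18e-04, 0.728), and activity-regulated genes, 0 of 16 (-0.33, 0.00212, 0.728). The oligodendrocyte call ended in hippocampus without the first untested C57BLKS/J or the tested C57BL6/J array (adjusted p up to 0.149), and in striatum without the second untested array of either strain (up to 0.194). The activity-regulated call ended without the tested C57BLKS/J or the second untested C57BL6/J array (up to 0.155). Single arrays moved its median between -0.61 and -0.19. The hippocampus count was 421 without the second untested C57BLKS/J array and 342 without the second untested C57BL6/J array. In striatum it was 168, 155 and 160 without the second untested C57BLKS/J and the first and second untested C57BL6/J arrays. In brainstem it was 187 and 217 without the tested and second untested C57BLKS/J arrays, 182 and 215 without the first and second untested C57BL6/J arrays, and 964 without the second untested C3H HeJ array.

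In C57L/J, Gdpd3, a lysophospholipase D gene, was higher by 6.12, 4.81 and 6.63, with each of the other strains at the floor (1.60 to 1.69). Cfap54, a cilia protein gene, was higher by 3.89, 4.64 and 1.37, and Wdfy1 by 2.49, 2.36 and 3.18. Stk25 was lower by -7.19, -6.79 and -6.97, Gm13306 by -7.63, -7.43 and -4.61, and Erdr1 by -6.79 ± 0.37, -8.57 ± 0.44 and -7.59 ± 0.22. Slc18a2, the vesicular monoamine transporter, was lower by -2.88 ± 0.18, -4.55 ± 0.48 and -1.20 ± 0.22. The counts were 541 in hippocampus (223 higher, 318 lower), 530 in striatum (266, 264) and 410 in brainstem (240, 170), with 116, 164 and 102 over 2-fold. The genes called in all 3 tissues were 55 higher and 81 lower, where independent lists would share 0.0953 and 0.0954. In brainstem the split was 180 higher and 199 lower after quantile normalization and 154 and 175 after median centring. Without the tested C57L/J array, the striatum count rose to 1883. The C57L/J arrays then left were the untested ones, on which cortical markers stood higher and striatal markers lower (below). With the cortical marker shift as a covariate the count was 343, so the rise is not separated from dissection. The striatum count was 797 without the tested BalbC/J array, 332 and 299 without the first and second untested C57L/J arrays, and 258 and 312 without those of C57BL6/J. The brainstem count was 270 and 252 without the tested and first untested C57BL6/J arrays and 1140 without the second untested C3H HeJ array.

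In C57L/J striatum, dopamine signalling genes were lower, 0 and 1 of 10 (7 adjusted over the list alone, median -0.39, camera adjusted p = 2.64e-04, adjusted p = 0.852 with an estimated correlation), as were striatal markers, 0 of 12 called (9, -0.48, 1.29e-04, 0.865). Activity-regulated genes there had 0 higher and 2 lower of 16 (5, -0.49, 0.00743, 0.865), with Egr2 at -1.47 and Junb at -1.38. The serotonin receptor gene Htr1b was lower by -1.13 ± 0.29. The arrays were uneven. On the tested, first and second untested C57L/J striatum arrays striatal markers stood at 0.12, -0.40 and -1.04 from the striatum median, dopamine signalling genes at -0.30, -0.48 and -0.79, and cortical markers at -0.72, 0.61 and 1.51. Striatal markers were therefore not lower on the tested array. Without the second untested array the striatal and dopamine medians were -0.20 and -0.17 (camera adjusted p = 0.00716 and 0.00281), and without the tested one -0.78 and -0.60. In hippocampus, hippocampal markers were lower, 0 and 2 of 14 (4, -0.23, 0.0434, 0.832), glucocorticoid-responsive genes lower with 0 of 14 called (-0.17, 0.0381, 0.832), and microglial markers higher, 2 and 0 of 10 (0.15, 0.0172, 0.694). C1ql2 was lower there by -1.61 ± 0.14. The hippocampal marker call ended on leaving out any 1 of 5 arrays and the glucocorticoid call any 1 of 4 (adjusted p up to 0.343 in both), and the microglial call without the first untested C57L/J or the tested C57BL6/J array (up to 0.106). Single arrays moved the hippocampal marker median between -0.35 and -0.10. Without the tested C57L/J array the glucocorticoid median was -0.38 (camera adjusted p = 4.16e-05), so this list rested on the untested arrays. The activity-regulated call in striatum ended without the second untested C57BL6/J array (0.101).

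Genes listed beforehand as varying between inbred strains were mostly higher in the other strains than in C57BL6/J where called. Of 9 measured members, 4 to 6 were called higher and 0 to 2 lower in each strain and tissue (5 to 8 adjusted over the list alone). Camera found the list higher in each strain and tissue, with medians of 0.07 to 1.19. Its members were chosen for known strain differences, so its passing is a check of the data and not a new finding. The 5 contrasts of a tissue share the same 3 C57BL6/J arrays, so their common direction is not 5 separate findings. Single arrays moved some medians, in hippocampus from 0.07 to 0.16 in C57BLKS/J (without its second untested array) and from 0.09 to 0.15 in C57L/J (without the tested array), in striatum from 0.42 to 0.21 in C57BL10/J (without the tested array), from 0.33 to 0.15 and 0.22 in C57BLKS/J (without its second untested and the first untested C57BL6/J array) or to 0.54 and 0.575 (without its tested and first untested array) and from 1.19 to 0.73 in C57L/J (without the second untested array), and in C57BL10/J brainstem from 0.27 to 0.18 (without the tested array), with the camera call kept. The calls that held with an estimated correlation were C57BL10/J and C57L/J in hippocampus (adjusted p = 0.0218 and 0.0387), BalbC/J and C57BL10/J in striatum (0.0448 and 0.0306) and all 5 strains in brainstem (0.00978, 0.0109, 0.0327, 0.00896 and 0.0177). Gabra2, the GABA-A receptor alpha 2 subunit, was higher in each strain and tissue by 1.33 to 2.08, for example in C3H HeJ by 1.89 ± 0.11, 1.55 ± 0.16 and 2.08 ± 0.11. Nnt, the mitochondrial transhydrogenase, was higher in BalbC/J by 1.31, 1.12 and 1.54. Alad, the second enzyme of haem synthesis, was higher by 2.01, 2.36 and 2.32 in C3H HeJ and not called in C57BLKS/J. Glo1, which detoxifies methylglyoxal, was higher by 1.25, 1.43 and 1.12 in C3H HeJ and by 1.23, 1.29 and 1.01 in C57BLKS/J. Over the strain contrasts, 56 of 500 list tests passed with the preset correlation and 9 with an estimated one, all 9 for genes known to vary. Of the 56, 33 passed with each array left out in turn, a check chosen after the data were seen. Lists not named had no camera call in a strain contrast under either setting.

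**Figure D2:**
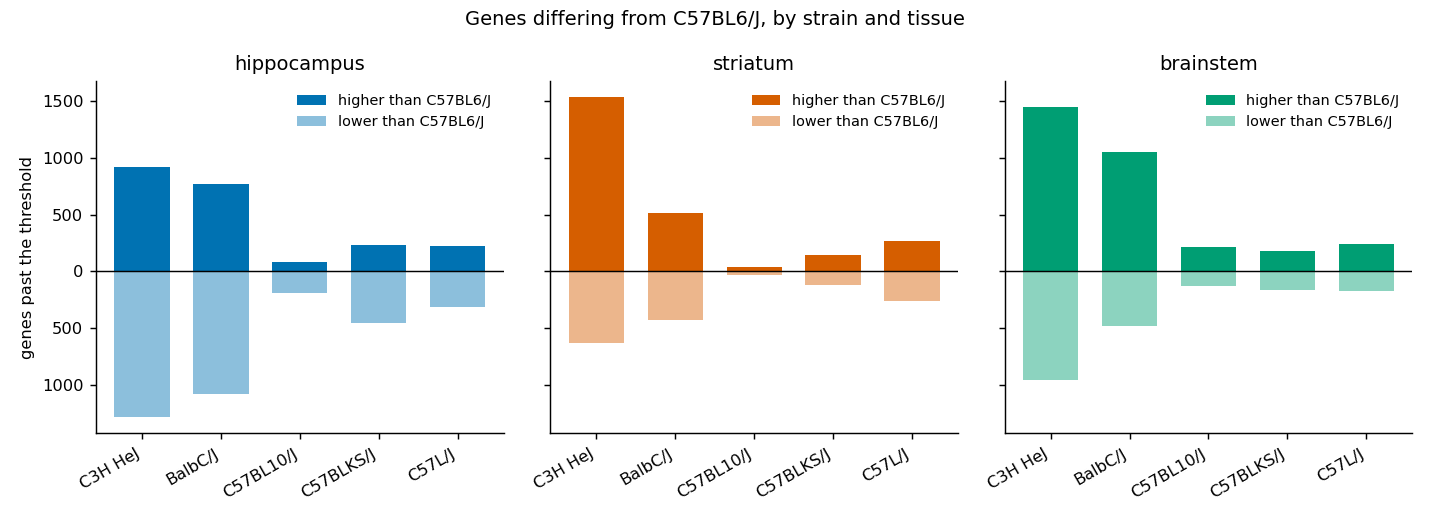
Number of genes called higher (upward) and lower (downward, vertical axis) in each strain (horizontal axis) against C57BL6/J, by tissue. C3H HeJ had the most calls in each tissue (2212, 2167 and 2408) and C57BL10/J the fewest in hippocampus and striatum (277 and 66).

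**Figure D3:**
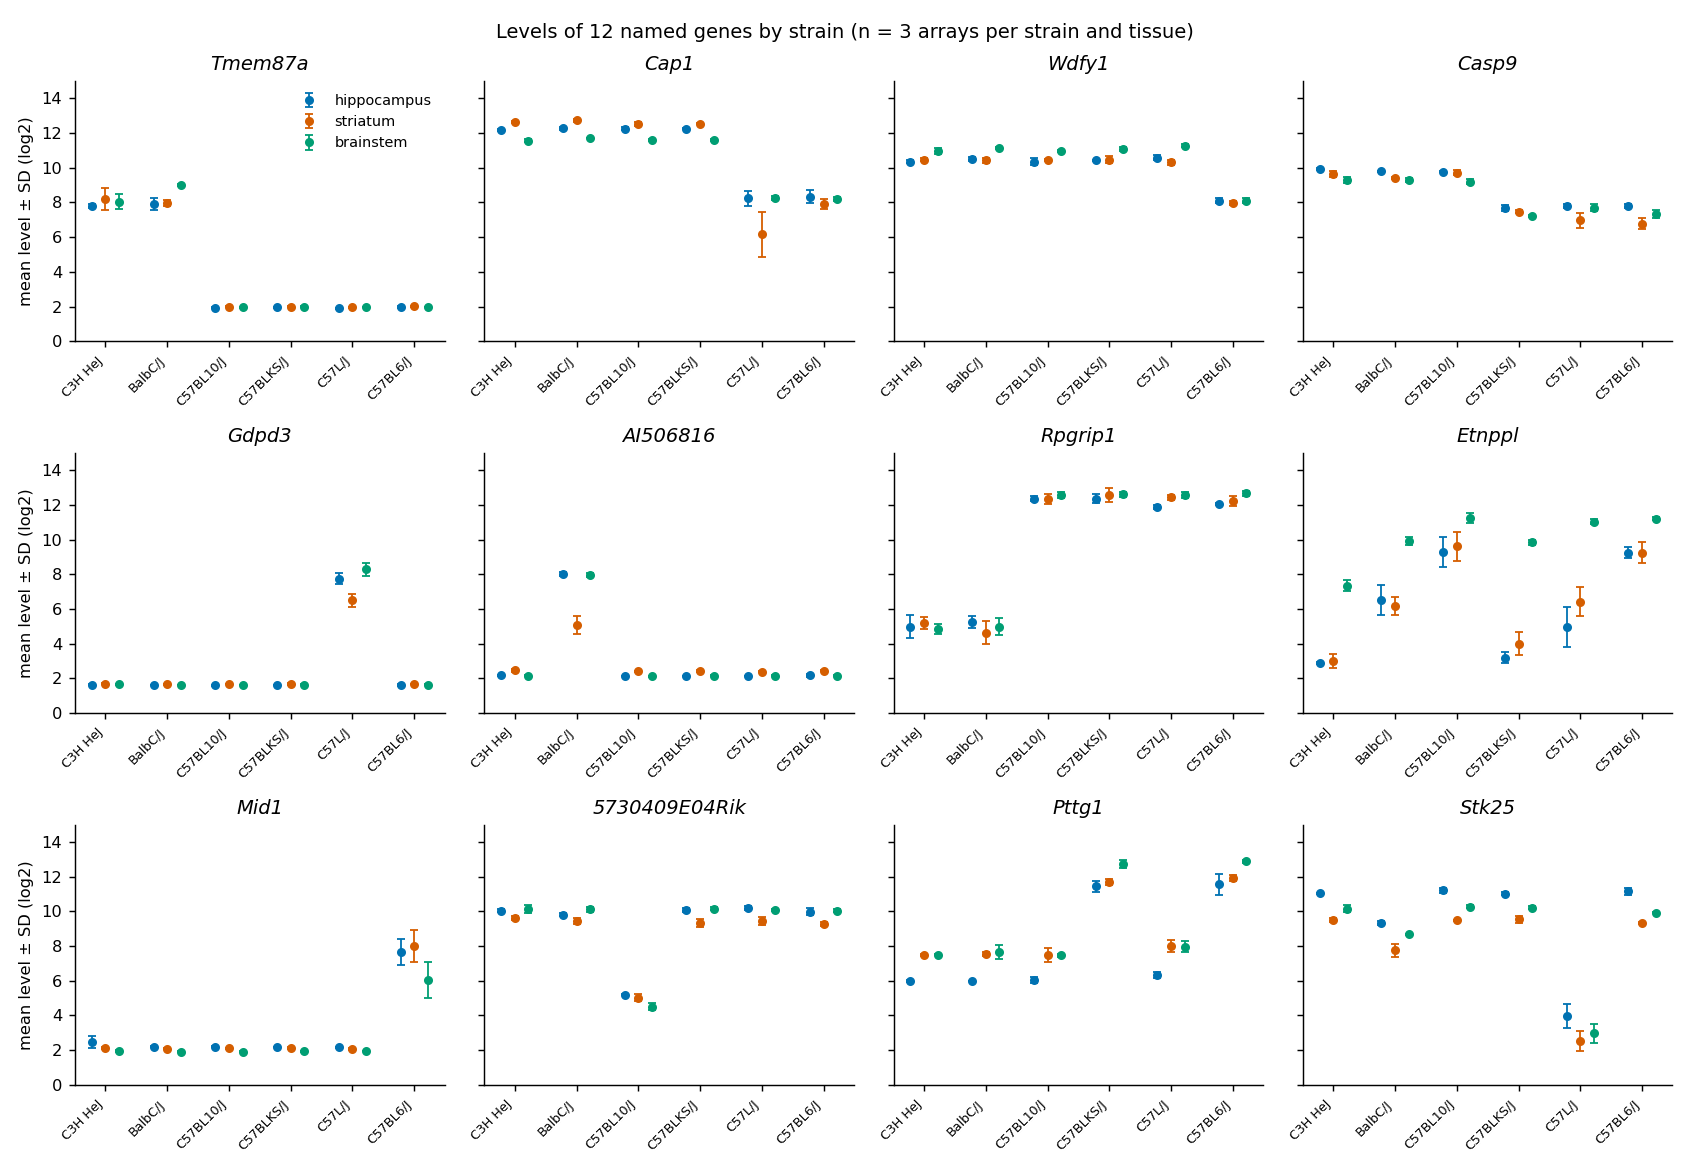
Log2 levels (vertical axis, mean with SD over 3 arrays) of 12 named genes by strain (horizontal axis) and tissue. Against C57BL6/J, Tmem87a was higher by 5.84 to 7.03 in C3H HeJ and BalbC/J, and Gdpd3 by 4.81 to 6.63 in C57L/J.

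The comparison of tested with untested mice asked whether expression differed after the testing sessions. The labels give postnatal day 50 for testing and postnatal day 60 for killing. A change that had faded by then could not be seen. In hippocampus the smallest p-values belonged to the potassium channel gene Kcnj4 (-0.34 ± 0.06), the kinase gene Pak6 (-0.29 ± 0.05) and Dipk2a (0.21 ± 0.04), each with an adjusted p of 0.323, then Fbxl19 (-0.32 ± 0.07) and the synaptic adhesion gene Lrfn3 (-0.61 ± 0.14) at 1.00. In striatum they were those of Cd24a (0.53 ± 0.10), Slc35a3 (0.19 ± 0.04), Zbtb20 (0.46 ± 0.10), Septin10 (0.41 ± 0.09) and Pwwp2a (0.19 ± 0.04), with adjusted p = 1.00. In brainstem they were those of Zfp87 (0.37 ± 0.07), Tspan13 (-0.12 ± 0.02), Rbm19 (0.30 ± 0.07), Trav9d-3 (0.53 ± 0.13) and Plce1 (-0.15 ± 0.04), with adjusted p = 0.986. Limma called 0 genes in each tissue, beside 488, 467 and 281 at an unadjusted p under 0.05. Testing took 2.55%, 2.89% and 1.88% of the variance. The chance level of 5.88% takes no account of strain, which took most of the variance, so these shares are not shown to lie under chance. Pdxdc1 differed by -0.01, 0.12 and 0.06 between tested and untested mice. Of test genes shifted by 1 log2 unit in simulated copies of the data, 100%, 94.0% and 97.0% were recovered at this array number. The copies had independent noise and many genes shifted at once, so they may overstate what the real arrays could call. Choroid plexus markers had medians of -1.06 in hippocampus and 1.28 in striatum without a call, so a shift over 1 could go uncalled.

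Of the gene lists, 13 passed camera for testing, with 0 members called in each, none passing with an estimated correlation, and none passing with each array left out in turn. In hippocampus activity-regulated genes had a median of 0.09 (camera adjusted p = 0.00812), heat shock genes 0.05 (0.00700), oligodendrocyte markers 0.09 (0.00618), endothelial markers -0.12 (0.0154) and choroid plexus markers -1.06 (0.00346), each with adjusted p = 0.733 with an estimated correlation. In striatum heat shock genes stood at 0.08 (0.0110), striatal markers at 0.13 (0.0153), cortical markers at -0.24 (0.0157), neuronal markers at -0.06 (0.0441), choroid plexus markers at 1.28 (3.28e-04) and ependymal markers at 0.36 (0.00326, 2 adjusted over the list alone), each with 0.764. In brainstem choroid plexus markers stood at -0.37 (3.48e-04, 0.902) and ependymal markers at -0.14 (0.0466, 0.720). Ttr differed by -1.23, 1.38 and -0.08 in the 3 tissues, so the sign of this choroid plexus transcript was not the same across tissues.

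The tissue comparison asked which genes mark each dissection. In hippocampus the highest were Lct (7.33 above the mean of the other two tissues, level 9.75 ± 0.33, SD, n = 18), the transcriptional regulator Prdm8 (7.12) and the glutamate receptor gene Grm2 (6.94), followed by Slc26a4, Rtn4rl2, Spink8, Neurod2, Grp, Cpne7 and Rasd1 at 6.93 to 6.56. In striatum they were the orphan receptor gene Gpr6 (9.97, level 13.45 ± 0.41), Ido1 (8.69), Sh3rf2 (8.37), Serpina9 (8.25) and the dopamine receptor gene Drd1 (8.19), then Gm6556, Rarb, the receptor gene Drd2, Tlnrd1 and Lrrc10b at 7.98 to 7.14. In brainstem they were the neuronal glycine transporter Slc6a5 (10.03, level 12.15 ± 0.28), the glycine receptor gene Glra1 (8.13) and the hindbrain patterning gene Hoxb5 (7.54), then Mab21l2, Kcng4, Ret, Irx3, Serpinb1b, Gpx3 and Baiap3 at 7.54 to 6.84. Of 13199 genes, 11341 were called in hippocampus (6955 higher, 4386 lower), 11866 in striatum (3318, 8548) and 11717 in brainstem (7153, 4564), with 2313, 3287 and 3564 over 2-fold. These splits rested on the scaling. Quantile normalization shifted the median of all genes by -0.15 in hippocampus and 0.23 in striatum, and median centring by -0.24 and 0.31. The hippocampus split became 5007 higher and 6445 lower or 4210 and 7303, and the striatum split 5409 and 6489 or 5966 and 5771. Pdxdc1 was highest in brainstem, at 0.61 (adjusted p = 1.92e-11), with -0.46 in striatum (1.67e-08) and -0.15 ± 0.06 in hippocampus (0.0260), a difference within those shifts. The hippocampus call ended on the next brightest probe set (-0.05), with untested arrays only (-0.12), and on leaving out the second untested C3H HeJ, first untested BalbC/J, tested C57BL10/J or tested C57BLKS/J hippocampus array (-0.13 to -0.14).

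Striatal markers were higher in striatum, 12 of 12 called (median 6.89, camera adjusted p = 2.80e-13, adjusted p = 0.0594 with an estimated correlation). Hippocampal markers were higher in hippocampus, 14 of 14 (5.07, 4.09e-07, 0.00245), and lower in brainstem, 12 of 14 (-1.88, 1.44e-04, 0.0405). Brainstem markers were higher in brainstem, 15 of 15 (5.41, 3.46e-05, 0.301). Dopamine signalling genes were higher in striatum, 7 of 10 (3.66, 1.50e-04, 0.104), and lower in hippocampus, 9 of 10 (-1.31, 3.21e-05, 0.0673). Glycine signalling genes were higher in brainstem, 6 of 7 (2.28, 0.0345, 0.301). Amine and GABA synthesis enzymes were higher in brainstem, 10 of 13 (1.12, 0.0345, 0.301), and lower in hippocampus, 10 of 13 (-0.76, 4.22e-04, 0.0673). Ionotropic glutamate receptors were higher in hippocampus, 11 of 15 (0.77, 0.0471, 0.0930). Oligodendrocyte markers were higher in brainstem, 10 of 10 (1.05, 0.0151, 0.484), and lower in hippocampus, 10 of 10 (-0.97, 3.21e-05, 0.269). Circadian genes were higher in striatum, 12 of 14 (1.18, 1.01e-05, 0.114), and lower in brainstem, 12 of 14 (-0.99, 0.00240, 0.301). Activity-regulated genes were higher in striatum, 11 of 17 (0.93, 0.00279, 0.449), and lower in brainstem, 11 of 17 (-2.36, 0.00107, 0.301). Microglial markers were higher in striatum, 6 of 10 (0.44, 0.00854, 0.554), and lower in brainstem, 8 of 10 (-0.53, 0.0161, 0.458). Ependymal markers were lower in hippocampus, 6 of 6 (-1.48, 0.00599, 0.273). Counts adjusted over the list alone were the same for each of these lists. Of 102 list tests between tissues, 26 passed camera at the preset correlation and 2 with an estimated one. Not all of the 26 are given here. Markers of neighbouring tissue did not pass, with cerebellar markers at 2.89 (8 of 9 higher, 0.157) and choroid plexus markers at 2.11 (9 of 9 higher, 0.240) in brainstem and cortical markers in hippocampus (5 of 7 higher, 0.631).

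**Figure D4:**
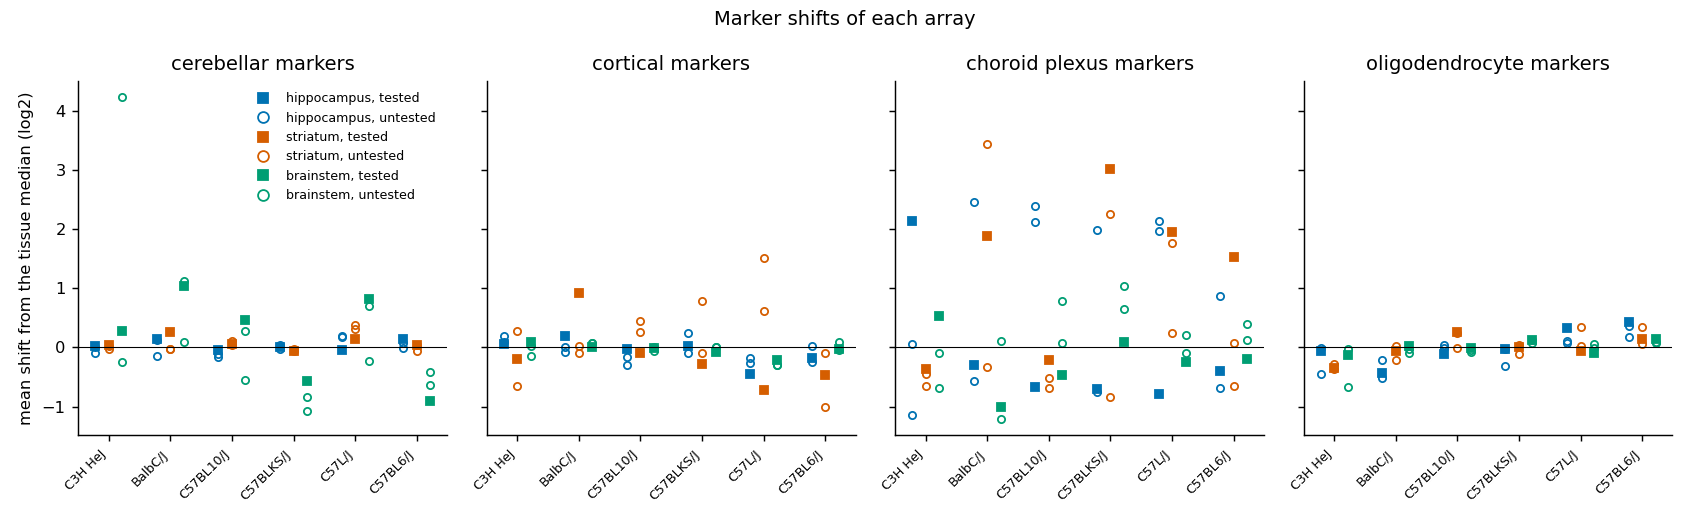
Mean log2 shift of marker lists (vertical axis) on each array from the median of its tissue, with a point per array. The second untested C3H HeJ brainstem array stood at 4.23 for cerebellar markers, where the other brainstem arrays lay between -1.07 and 1.13.

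The interaction of strain with tissue asked whether a strain difference in a tissue held in another. Lamb3, a laminin subunit gene, had the largest F (466, adjusted p = 4.02e-31), being higher in BalbC/J striatum by 4.53 (level 7.08 ± 0.26, SD, n = 3) and at the floor elsewhere. Ahnak2 (F = 315) was lower in C3H HeJ brainstem by -6.32 and at the floor in the other two tissues. Cldn23, a claudin gene (F = 271), was higher in C3H HeJ striatum by 4.44. Baiap2l1 (F = 210) was higher in BalbC/J and C3H HeJ hippocampus, with low levels in striatum and brainstem of both strains. Mir1931 (F = 125) was lower in C57L/J by -5.14, -6.87 and -0.98. H2-Bl, an MHC class I gene (F = 107), was higher in C57L/J brainstem by 5.21 against 0.56 and 0.12 in hippocampus and striatum. The next were AI506816 (F = 89.8), B230311B06Rik (F = 88.1, -2.75 in C57BLKS/J brainstem), Abhd14a (F = 74.5, -0.92, -3.20 and -0.52 in BalbC/J) and Gm33738 (F = 73.3, -1.65 in C57L/J brainstem). For Lamb3, Ahnak2, Cldn23, Baiap2l1, B230311B06Rik and Gm33738 another tissue lay under the filter, so the test sets a tissue with signal against one without and cannot compare strain differences there. For Mir1931 in C57L/J and AI506816 in BalbC/J, 1 of the 2 strains compared lay at the floor, so the values follow the level of the other strain in each tissue. In all, 2294 genes were called, in a model that takes no account of mice shared between tissues. Without the tested BalbC/J and C57L/J striatum arrays and the second untested C3H HeJ brainstem array, a choice made after the data were seen, 4669 were called. Pdxdc1 was past the threshold narrowly (F = 3.09, adjusted p = 0.0395), but the call did not hold throughout. It ended with no filter (F = 3.11), after median centring (2.85), with the replicate block (3.07), on the next brightest probe set (1.86), with untested arrays only (1.41), and on leaving out any 1 of 17 arrays (7 of hippocampus, 5 of striatum and 5 of brainstem, F = 2.50 to 2.99). The interaction of testing with tissue called 0 genes by limma (397 at an unadjusted p under 0.05), with the largest F for Trav9d-3 (12.4), Zbtb20 (11.7) and the protocadherin gene Pcdhb15 (11.6), each at adjusted p = 0.556. Without the tested C57BLKS/J striatum array 1 gene was called, Pcdhb15 (F = 18.9).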

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

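Of the tests in this part, those of mislabelled arrays, of probe mismatch and of transcript amount at Pdxdc1, and those of cerebellar tissue and of a wrong strain label for the brainstem array, were chosen only after the result was seen.

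Strain differences from C57BL6/J were compared between tissues by a test of the difference itself. Of 23 genes named in the strain comparisons, 15 passed the interaction test. Another 7 (Lamb3, Ahnak2, Cldn23, H2-Bl, B230311B06Rik, Abhd14a and Gm33738) were named for their small interaction p, so their passing adds nothing. Each is given here by the pair of tissues farthest apart. For Lamb3, Baiap2l1, Ahnak2, Cldn23, B230311B06Rik and Gm33738, 1 tissue of the pair lay under the filter, so the value sets a tissue with signal against one without and does not show an unequal strain difference. For AI506816, Gdpd3, Mid1, Mir1931 and Tmem87a, 1 of the 2 strains lay at the floor in both tissues, so the value follows the level of the other strain and does not show one either. Lamb3 differed by 4.56 more in BalbC/J striatum than brainstem, Baiap2l1 by 8.03 more in BalbC/J hippocampus than brainstem, AI506816 by 3.20 more in BalbC/J hippocampus than striatum, Abhd14a by -2.68 in BalbC/J striatum against brainstem, and Tmem87a by -1.08 in BalbC/J hippocampus against brainstem. In C3H HeJ, Ahnak2 differed by 6.37 between hippocampus and brainstem, Cldn23 by 4.41 and Cfap54 by 3.57 between striatum and brainstem, and Pdxdc1 by 0.67 between hippocampus and striatum (interaction adjusted p = 0.0395, pair adjusted p = 0.0934, a call that ended on leaving out any 1 of 17 arrays). In C57L/J, striatum against brainstem, Mir1931 differed by -5.89, H2-Bl by -5.10, Mid1 by -1.84, Gdpd3 by -1.83, Cap1 by -1.79, Wdfy1 by -0.83 and Gm33738 by 1.62. Also in C57L/J, Gm13306 differed by -3.02 between hippocampus and brainstem and Pttg1 by -1.30 between hippocampus and striatum. In C57BL10/J, 5730409E04Rik differed by 1.26 and Casp9 by 1.07 between striatum and brainstem. In C57BLKS/J, Etnppl differed by -4.68 between hippocampus and brainstem and B230311B06Rik by 2.72 between striatum and brainstem.

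Among the 6 tested arrays of a tissue, a single array stood far from the others at 2 genes. Zbtb20 was 12.07 on the C3H HeJ striatum array, with the others at 11.52 to 11.72, and Zfp87 was 5.55 on the C57BL6/J brainstem array, with the others at 4.86 to 5.03. In all, 18 groups were tested this way, and chance gives about 1 in 20.

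At Pdxdc1, 1 probe set was much higher and the other 3 lower in C3H HeJ and BalbC/J than in the C57 strains. A swap of arrays between C3H HeJ or BalbC/J and the C57 strains is argued against, since 54 of 54 arrays lay on their labelled side. A swap within either group would not show this way. The tests of mismatch and of amount restate the pattern, which was defined by probe sets going both ways, so they could not have failed. A probe mismatch that only lowers signal in strains other than C57BL6/J would not give the rise of at least 7.19 in C3H HeJ in every tissue. A different total amount of transcript alone would not give both directions. Of 12 tests of a probe set in a tissue, 9 were lower and 3 higher in C3H HeJ. Transcript forms that differ between strains, or sequence variants under probes designed on other strains, may each account for the pattern, and neither was tested because probe sequences are not given in the sources used here.

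The second untested C3H HeJ brainstem array correlated least with its strain. Its cerebellar markers stood 4.23 above the brainstem median, where the other arrays lay between -1.07 and 1.13, with Car8 at 15.2 (median of the others 11.05), Zic1 at 14.9 (12.63), Pcp2 at 14.6 (8.91), Gabra6 at 14.5 (8.80) and Cbln3 at 14.4 (7.81). Cerebellar tissue in the pool is a candidate explanation, with brainstem markers at -1.24 and oligodendrocyte markers at -0.67, although the brainstem arrays express 9 of the 9 listed genes and 1 is on another list too. Degraded RNA is argued against by the 3' to 5' difference of Actb, 0.754 within 0.621 to 0.820 on the others, and a wrong strain label by the correlation with its own strain over 3765 genes, 0.581 against 0.229 for the next, BalbC/J. No biological explanation was tested, and strain remains open for the other C3H HeJ brainstem differences.

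Many strain differences over 2-fold on a gene's brightest probe set were not matched on its next. A match was judged by sign and size, so an unmatched gene may still differ the same way on its next probe set. In C3H HeJ, 59.2%, 68.1% and 62.8% of differences were matched in hippocampus, striatum and brainstem, against 92.1%, 87.2% and 90.1% of tissue differences, a gap of -19.1 points in striatum (95% interval -30.8 to -9.08), -32.9 in hippocampus and -27.3 in brainstem. In C57L/J fewer were matched, 37.1%, 56.4% and 39.5% in hippocampus, striatum and brainstem. BalbC/J and C57BLKS/J had 51.5% to 63.0% matched. C57BL10/J had 84.6% of 13, 81.8% of 11 and 75% of 12 matched in the same tissues. The intervals of its gaps ran from -34.4 to 3.95, -34.9 to 8.01 and -43.3 to 1.21 points, so no gap was shown there. Sequence variants under the probes may explain the C3H HeJ gap, as may transcript forms that differ between strains. If the probes had been designed on C57BL6/J alone, unmatched differences would be mostly lower. In C3H HeJ, 56.5% of 23 were lower in striatum (34.5 to 76.8%), 58.6% of 29 in hippocampus and 56.3% of 32 in brainstem. With so few genes the interval spans both outcomes, so that explanation cannot be told apart from its absence.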

How the results depend on the processing

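Leaving out the doubted arrays (the tested BalbC/J and tested C57L/J striatum arrays and the second untested C3H HeJ brainstem array), adding cerebellar, cortical or choroid plexus marker shifts as covariates, and leaving out each array for the gene lists were tests chosen only after the result was seen. The other alternatives were chosen before the data were examined. Counts of genes were within 1.5 times in 287 of 335 comparisons, and 48 moved further. Named genes kept direction and call in 2243 of 2269 comparisons. Of the rest, 22 lost the call and 4 changed sign, to small values of 0.0113 to 0.0762. All 4 sign changes and most of the lost calls came with the next brightest probe set. Genes without a next probe set, or with one under the filter, were left out of that setting and not counted as changed. Most other settings keep the same probe set, so the total says little about how named differences hold on another. Another 17 signs changed at values never called. Probe set C of Pdxdc1, on which the C3H HeJ and BalbC/J differences reversed (below), is not in these numbers.

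With every probe set tested separately, which by construction counts more features, the 6-strain counts were 8979 in hippocampus, 6613 in striatum and 6130 in brainstem. In the same order the counts were 5444, 4603 and 5053 for C3H HeJ, 3974, 2067 and 2971 for BalbC/J, 693, 142 and 1067 for C57BL10/J, 1742, 601 and 753 for C57BLKS/J, and 1362, 1121 and 975 for C57L/J. Tissue counts were 25635, 26765 and 26266, and strain by tissue 4918. On probe set C of Pdxdc1 the differences reversed, to 7.82, 7.19 and 7.62 in C3H HeJ and 7.94, 7.68 and 7.99 in BalbC/J, and on probe set D the BalbC/J striatum difference weakened to -0.34.

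The mean of the probe sets ended the 6-strain call of Pdxdc1 in hippocampus (0.2703). With the next brightest probe set, Rpgrip1 changed sign to small values, 0.0762 and 0.0113 in C3H HeJ hippocampus and striatum and 0.0437 in BalbC/J hippocampus. Rps9 likewise changed to 0.0704 in BalbC/J striatum. Median centring gave 98 and 194 genes in C57BL10/J hippocampus and brainstem and 391 in C57BLKS/J hippocampus. With untested arrays only, which has fewer arrays, brainstem counts fell to 1065 over the 6 strains, 1101 in C3H HeJ, 532 in BalbC/J, 27 in C57BL10/J, 117 in C57BLKS/J and 180 in C57L/J; striatum counts were 595 in BalbC/J and 152 in C57BLKS/J but rose to 1395 in C57L/J. Without the doubted arrays, brainstem counts rose to 4701 over the 6 strains, 3157 in BalbC/J, 1517 in C57BL10/J, 964 in C57BLKS/J and 1140 in C57L/J, that of C57L/J striatum to 2045 and that of strain by tissue to 4669. With the cerebellar covariate the brainstem counts were 4835, 3129, 1298, 783 and 1192 in that order, and with the cortical covariate C57L/J striatum had 343. The rises in C57L/J striatum to 1395 and 2045 kept only its untested arrays, on which cortical markers stood above the striatum median. With an estimated correlation, 11 of the 95 list calls stayed. The replicate block left every count within 1.5 times (3607 for the 6 strains in hippocampus) and ended the strain by tissue call of Pdxdc1 (F = 3.07). Except for the number of features or arrays, the cause was not tested.

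Leaving out each array in turn, the 6-strain counts ranged from 3152 to 4335 in hippocampus, 2307 to 4223 in striatum and 2202 to 4701 in brainstem (the last without the second untested C3H HeJ array). In hippocampus, striatum and brainstem the ranges were 1508 to 2830, 1285 to 2396 and 1404 to 3307 for C3H HeJ, 1257 to 2126, 578 to 1052 and 971 to 3157 for BalbC/J, 90 to 426, 36 to 75 and 105 to 1517 for C57BL10/J, 342 to 924, 155 to 294 and 182 to 964 for C57BLKS/J, and 390 to 785, 258 to 1883 and 252 to 1140 for C57L/J. Tissue counts ranged from 11164 to 11395, 11782 to 12034 and 11661 to 11746, strain by tissue from 1869 to 3436, testing by tissue from 0 to 1 (without the tested C57BLKS/J striatum array) and testing from 0 to 0. Of the list calls, 33 of 56 for strains and 0 of 13 for testing passed whichever array was left out. The pools left in a strain were taken to vary like those of other strains.

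Signal over background limits these values. A fold against a group at the floor, as for Tmem87a, Gdpd3, Mid1 or Pdxdc1 on probe set C, depends on where the background correction put that floor. Of genes shifted by 0.5 in simulated copies, 56.7% to 62.7% were recovered in a strain contrast and by 1, 89.6% to 92.5%. With independent noise and many genes shifted at once, the copies may overstate what the real arrays could call.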

Other observations

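The test of neighbouring genes was planned before the result was seen, whereas the counts over other splits of the arrays were tests chosen only after it.

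Of the 30 genes called in all 3 tissues between C57BL10/J and C57BL6/J, 10 were among the 706 genes tested on chromosome 4 and 10 among the 906 on chromosome 11. In C57BLKS/J, 20 of 114 were on chromosome 11 (906 tested), 12 on chromosome 1 (680 tested) and 12 on chromosome 17 (520 tested). In C57L/J 16 of 136 were on chromosome 1 (680 tested) and 11 on chromosome 13 (451 tested). By share of the genes tested, chromosome 1 did not stand out in C57L/J. Casp9, named above in C57BL10/J, was also at 9.94 in C3H HeJ and 9.81 in BalbC/J hippocampus, near its C57BL10/J level of 9.78, against 7.81 in C57BL6/J. Pttg1 was at 11.5 to 12.9 in C57BL6/J and C57BLKS/J and at 5.99 to 8.01 in the other 4 strains. Cap1 was at 8.34, 7.91 and 8.20 in C57BL6/J and at 8.23, 6.16 and 8.24 in C57L/J, about 4 below the other 4 strains in hippocampus.

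A hypothesis was that genes differing between close strains sit together in inherited segments that differ between the strains. Called genes would then be next to each other more often than by chance. In C57BL10/J brainstem, the smallest ratio, 17 neighbouring pairs were seen against a mean of 9.31 over permutations (ratio 1.83, permutation p = 0.01), with a highest of 25 and with 17 pairs among tissue differences as well. In the other 8 comparisons the ratio was 2.21 to 25.3 and above every permutation (p = 1e-04, the smallest 10000 permutations can give). In hippocampus, strain pairs, permuted mean and tissue pairs were 23, 6.15 and 6 in C57BL10/J, 84, 37.95 and 53 in C57BLKS/J and 72, 23.56 and 34 in C57L/J. In striatum they were 9, 0.36 and 0, 27, 5.85 and 4, and 57, 22.72 and 25, and in brainstem 33, 9.34 and 17 in C57BLKS/J and 41, 13.28 and 23 in C57L/J. Tissue pairs were above the permuted mean in 5 of the 8, so the ratios overstate the excess there. Inherited segments that differ between the strains may account for what remains in those 8, but the brainstem value keeps the hypothesis open as a whole.

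Chance is argued against for the 6-strain counts, since 1 of 100 splits, the real one, gave as many genes. That is the smallest share these splits can give. The real count was 3838 against at most 171 in hippocampus, 3228 against 1784 in striatum and 2872 against 204 in brainstem. For the tissues the share was the same (11341 against 6594 in hippocampus, 11866 against 6546 in striatum, 11717 against 6218 in brainstem). The tissue splits take no account of the mice shared across tissues. For strain by tissue the real count was 2294 against at most 269. Those splits shuffled strain within each tissue, which breaks up the strain differences themselves. They therefore cannot show whether chance made strain differences unequal between tissues.

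For testing, and for testing by tissue, the real count was 0, so 100 of 100 splits gave as many by construction and that count decides nothing (highest others 8, 5 and 0 for testing, 179 for testing by tissue). At an unadjusted p under 0.05, 55, 52 and 66 of 100 splits gave as many genes as the real 488, 467 and 281, so chance cannot be excluded for testing.

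Each strain against C57BL6/J has only 10 splits, too few for a share under 0.05, and in each comparison 1 of 10, the real one, gave as many genes. In hippocampus the real and highest other counts were 2212 and 655 for C3H HeJ, 1854 and 7 for BalbC/J, 277 and 7 for C57BL10/J, 686 and 59 for C57BLKS/J and 541 and 85 for C57L/J. In striatum they were 2167 and 1, 946 and 2, 66 and 1, 268 and 0, and 530 and 2, and in brainstem 2408 and 0, 1534 and 1, 343 and 0, 342 and 0, and 410 and 0, in the same order.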
